A study of Mus musculus with 23 samples.

How the data were processed

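Endometrial RNA was measured by bulk RNA sequencing in 23 libraries, each made from the endometrium of 1 uterine horn of a C57BL/6 mouse. Per the labels' protocols, the endometrium was pressed out of the horn and so parted from the myometrium by hand, and poly(A) RNA was turned into stranded libraries and sequenced as single-end reads on an Illumina NextSeq. The groups came from the library titles: 6 SHAM, 5 PBS, 6 HG and 6 HG+ORG horns. PBS stands for saline, HG for a hydrogel, and HG+ORG for the hydrogel with human endometrial organoids. Injection followed 4 days after ethanol damage and tissue was taken 2 weeks later. What the SHAM horns received is not given in the sources used here. The PBS, HG and HG+ORG horns are called injured below.

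The deposited table held raw read counts per gene, as whole numbers that summed to different totals in each library. Per the submitters' processing notes, the tools were FastQC 0.11.9, MultiQC 1.27.1, Trimmomatic 0.39, HISAT2 2.2.1, SAMtools 1.21, featureCounts 2.0.3 of the Subread package, R 4.3.1 and DESeq2 1.42.1, on mouse genome build GRCm39. Their settings, the annotation release and the strand setting are not given in the sources used here. Antisense and overlapping genes and near-identical copies, such as the hemoglobin, Sprr2, Mcpt and immunoglobulin genes, may therefore share reads, and their values are uncertain. The alignment to the mouse genome does not tell reads of human organoid cells apart from mouse reads. The table held 18682 features, each with at least 10 counts in at least 3 libraries, so a low-count filter appears to have been applied before deposit. Of these, 18341 had a gene symbol and 341 had only an identifier. The reference annotation at hand was of another build than GRCm39, so no coordinates are given.

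Total counts per library ranged from 7920920 to 14903000, with a median of 12701400. edgeR 4.0.16 in R 4.3.3 was run on the counts as deposited, with trimmed mean of M-values (TMM) factors and filterByExpr by group, which kept 17708 features and removed 974. All 4 groups entered 1 quasi-likelihood fit with no covariates, so that they shared an estimate of the spread. The 6 pairwise contrasts were tested with Benjamini-Hochberg adjustment at 0.05 and no fold minimum. Expression levels are log2 CPM (counts scaled to a common library size) with a prior count of 2, given as mean ± SD over horns. Fold changes are edgeR's log2 values. Their standard errors (SE) are not given by edgeR but were derived as the absolute log2 fold over the square root of the test's F statistic. A fitted fold compares mean counts, so where horns of a group differ widely it can differ in size and even in sign from the difference of mean log2 CPM.

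Gene lists of cell types, pathways and tissue quality, 29 in all with 382 distinct members of which 353 were tested, were compared between groups by camera with a preset correlation between genes of 0.01, adjusted over the 29 lists of a comparison. The same test with an estimated correlation was an alternative. A list score is the mean log2 CPM of its tested members in a library. List scores were also compared by an exact two-sided permutation test over horns, adjusted over the 29 lists, which was added after the data had been seen. A member is counted as higher or lower by the sign of its fitted fold, whether or not it passed. List members were counted as called over all genes and also adjusted over the list alone. The lists were collagens and fibrosis, matrix remodelling enzymes, uterine epithelium, uterine glands, endometrial stroma, smooth muscle, macrophages and monocytes, neutrophils, T and NK cells, B and plasma cells, mast cells and eosinophils, inflammatory cytokines, interferon response, antigen presentation, endothelium, angiogenic factors, cell cycle, estrogen-responsive and progesterone-responsive uterine genes, implantation and receptivity, growth factors, Wnt targets and progenitor markers, ciliated and oviduct cells, squamous cells, adipocytes, mesothelium, erythrocytes, immediate early and heat shock genes, and mitochondrially encoded genes. Some genes stand in more than 1 list, for example Hoxa10, Hoxa11, Wnt4 and Fgf2.

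The groups, contrasts, tests, lists, alternative settings and the rule for naming genes were set before the data were examined. For PBS vs SHAM, HG vs PBS, HG+ORG vs PBS and HG+ORG vs HG the rule took up to 6 higher and 6 lower genes by fold among those past the threshold with a mean of at least 1 CPM and an established symbol. No gene passed, so this part was empty. The rule then took the 3 higher and 3 lower genes with the smallest p, said not to pass, for which the same limits on level and symbol were kept. It also took the 2 leading members of up to 6 lists past the list test, and always Col1a1, Col3a1, Tgfb1, Vegfa, Igf1, Esr1, Pgr, Mki67, Foxa2, Lif, Hoxa10 and Adgre1. Members of the lists may be named with their list, and any other gene named was chosen after its values were seen. One leading member that the rule names is not reported here.

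The labels give no animal for a horn. The 23 horns came from at most 21 mice, so some must share an animal, and which ones is not known. All tests, the permutation tests included, treat horns as independent, so p-values over horns may be too small. Replicate numbers run through the series and pair nothing. Whether the change from PBS to HG or HG+ORG runs against the change from SHAM to PBS was measured as a slope over all tested genes. The 5 PBS libraries were split into disjoint parts for the pair of changes, in all 20 assignments, because shared PBS libraries give a negative slope by chance alone.

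The scripts were tested on simulated counts drawn from the means and library sizes of these libraries, with 17708 features in each fit and 50 genes changed at each fold. In the simulation of PBS vs SHAM, edgeR recovered 28% of 2-fold, 68% of 4-fold, 84% of 8-fold and 98% of 16-fold changes. The shares in the same order were 14%, 68%, 96% and 96% for HG vs PBS, 10%, 66%, 94% and 92% for HG+ORG vs PBS, 24%, 80%, 84% and 84% for HG+ORG vs HG, 36%, 72%, 84% and 92% for HG vs SHAM, and 24%, 68%, 84% and 86% for HG+ORG vs SHAM. False calls numbered 2 for PBS vs SHAM, 9 for HG vs PBS, 8 for HG+ORG vs PBS, 4 for HG+ORG vs HG, 8 for HG vs SHAM and 4 for HG+ORG vs SHAM. A list of which every member was moved 2-fold passed the list test for PBS vs SHAM (adjusted p = 0.0157) and HG+ORG vs HG (0.0104). It was missed for HG vs PBS (0.102), HG+ORG vs PBS (0.886), HG vs SHAM (0.500) and HG+ORG vs SHAM (0.144), and 0 other lists were called. The simulation has no horn that stands apart and no shared change in cell mixture.

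The alternative settings fixed beforehand were relative log expression factors, DESeq2 1.42.0, limma 3.58.1 (voom with sample quality weights), no low-count filter, a mean of at least 1 CPM, the compared groups alone, a fold minimum, the smooth muscle or estrogen-responsive score as covariate, and leaving out each library in turn. Alternatives chosen after the data had been seen were summing SHAM replicates 5 and 6, leaving out HG+ORG replicate 18 together with that sum or with DESeq2 or limma, the epithelium score as covariate, the permutation test of list scores with its own left-out libraries, and a comparison of all 17 injured horns with SHAM.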

Results

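The data were gene counts from the endometrium of 23 mouse uterine horns, 6 SHAM, 5 PBS, 6 HG and 6 HG+ORG, from a model in which ethanol damages the endometrium and saline, a hydrogel or the hydrogel with human endometrial organoids is injected afterwards. SHAM replicate 4 had the lowest total, 7920920 counts, and PBS replicate 7 the highest, 14903000. Mitochondrially encoded genes took 1.50 to 11.4% of counts and the 10 most abundant features 3.94 to 15.4%.

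The horns differed widely within groups, and not in the same lists in each group. The smooth muscle score, the mean log2 CPM of 14 contractile genes, was 1.93 ± 0.38 (SD, n = 6) in SHAM, 2.59 ± 2.66 (n = 5) in PBS, 4.61 ± 1.79 (n = 6) in HG and 1.89 ± 1.43 (n = 6) in HG+ORG. The adipocyte score, which covers fat-cell genes such as Adipoq and Plin1, ran from -0.37 to 7.37 in SHAM and from -0.63 to 9.51 in HG. The cell cycle score was 1.62 in SHAM replicate 3, against a mean of 5.90 ± 2.12 (n = 6) over SHAM, and the neutrophil score was 1.72 ± 2.12 in SHAM and 3.21 ± 2.56 (n = 6) in HG+ORG. The leading 3 principal components of the 500 most variable features held 41.0, 19.7 and 12.4% of the variance.

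HG+ORG replicate 18 stood apart from the rest. Its macrophage and monocyte score was the highest of its group, at 8.63 against a group mean of 5.33 ± 1.84 (n = 6), and its epithelial score the lowest, at 5.38 against 8.04 ± 1.36. Esr1, the main uterine estrogen receptor, was at 3.82 log2 CPM in it and at 8.07 or more in every other library. Lyz2, the lysozyme of macrophages and neutrophils, was at 13.89 in it and at most 9.73 elsewhere. SHAM replicates 5 and 6 lay closest together of the 55 pairs within groups, with a chi-square per degree of freedom of 2.9, against 17.9 for the next pair and a median of 123.9. They were counted as separate horns because the titles give them as separate libraries, and the counts do not show whether they share an animal or a sample.

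**Figure D1:**
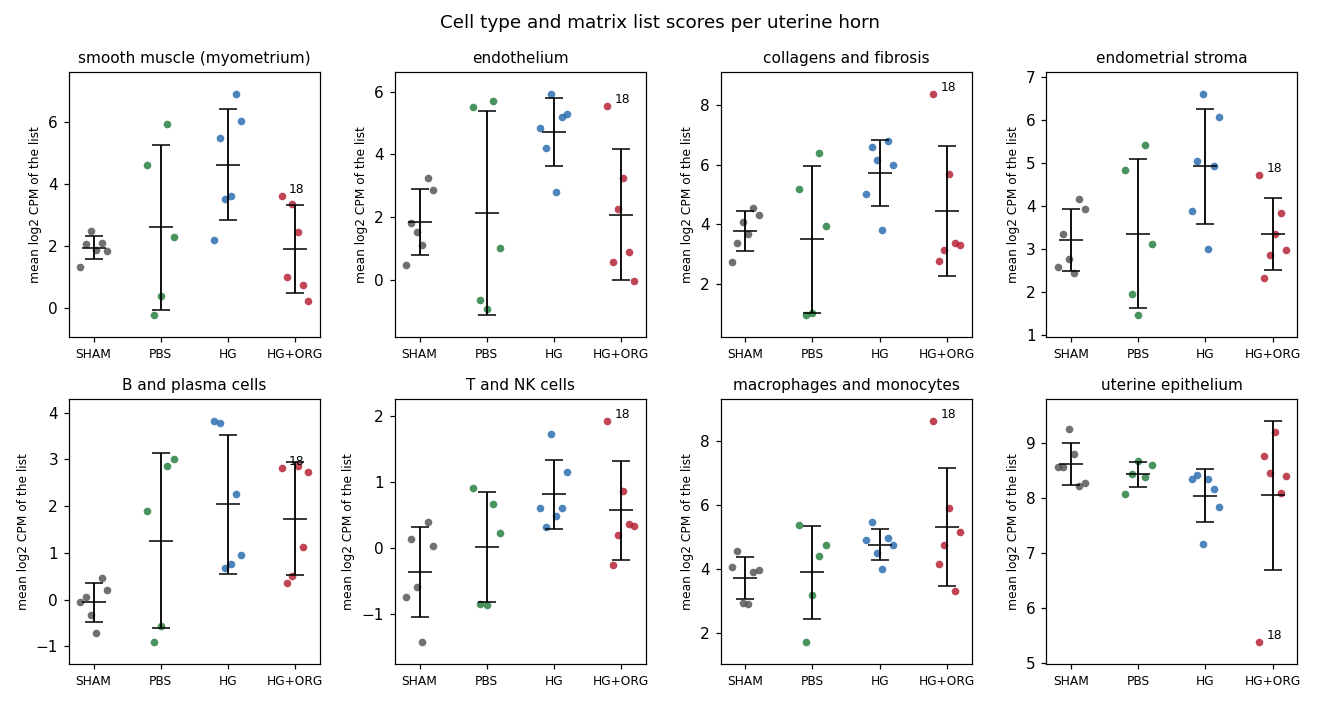
Scores of 8 gene lists (mean log2 CPM of the list, linear axes) in each uterine horn by group; points are horns (6 SHAM, 5 PBS, 6 HG, 6 HG+ORG), the horizontal mark and bars give the mean ± SD, and the number 18 marks HG+ORG replicate 18. The smooth muscle mean is 4.61 in HG against 1.93 in SHAM, and replicate 18 has the lowest epithelial score, 5.38.

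The contrast of PBS with SHAM sets damaged horns, 2 weeks after the saline injection, against SHAM horns. What the SHAM horns received is not given, so damage cannot be told apart from injection or timing. Immunoglobulin transcripts were higher in some PBS horns. Jchain, which joins secreted antibody chains, was at 1.27 ± 3.43 log2 CPM (SD, n = 5) in PBS and -1.38 ± 0.69 (n = 6) in SHAM, a fitted log2 fold of 5.13 (SE 1.58, adjusted p = 1.00), and Iglc2, a light chain constant gene, had a log2 fold of 5.34 (SE 1.40). Red cell genes were higher too, with Hbb-bt at 3.26 ± 3.60 in PBS and 1.66 ± 1.48 in SHAM. Smooth muscle genes such as Myocd, the activator of the contractile programme, and Synpo2 had log2 folds of 4.58 (SE 1.42) and 2.13 (SE 0.77), while the fat-cell genes Lep and Plin1 had -3.38 (SE 1.79) and -3.44 (SE 2.04). Iglc2 and Myocd were near the floor of -2.66 log2 CPM in SHAM (-2.3 ± 0.4 and -2.5 ± 0.3). In PBS they were at -0.24 ± 2.3 and -0.85 ± 1.9, so their folds rest on low counts. None of these genes passed.

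Of the 29 lists, 13 passed the preset-correlation test between PBS and SHAM, 6 higher and 7 lower. In 5 of 5 erythrocyte genes (median log2 fold 2.38), 5 of 6 B and plasma cell genes (3.17) and 9 of 9 adipocyte genes (-2.58) the fitted fold went the way of the test, and these calls held without any 1 library. The erythrocyte median was 1.48 and the adipocyte median -9.01 without PBS replicate 7. Leaving out 1 library at a time does not show that the PBS horns were split. As differences from the SHAM mean, erythrocyte scores were 4.51, 1.75 and 3.79 in PBS replicates 7, 10 and 11. They were -1.71 and -0.77 in PBS replicates 8 and 9. B and plasma cell scores were 1.95, 2.92 and 3.06 in the former and -0.84 and -0.5 in the latter. Adipocyte scores were -4.57 to -3.4 in PBS replicates 8 to 11 and 1.69 in replicate 7, against -4.26 to 3.48 in SHAM. Adjusted over the list alone, 5 erythrocyte and 4 B and plasma cell members were called, and 0 in the other lists. Smooth muscle was higher in 14 of 14 members (2.34), a call that ended without PBS replicate 10 (1.19, adjusted p = 0.540). Endothelium was higher in 12 of 13 (2.40), a call that ended without SHAM replicates 1 and 2 or PBS replicates 7 and 10 (adjusted p = 0.194, 0.0627, 0.804 and 0.714). Its median was -0.67 with limma (adjusted p = 0.289) and -0.66 with the smooth muscle score as covariate (adjusted p = 0.0501). With an estimated correlation no list passed, the smallest value being adjusted p = 0.419 with an estimated correlation. The exact permutation test of list scores passed none either (smallest adjusted p = 0.953).

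The calls of lists with smaller differences in the preset test also ended when any of several single horns was left out. Mitochondrially encoded genes were higher in 13 of 13 members, which ended without SHAM replicates 4 and 6 or PBS replicate 7 (adjusted p = 0.0516, 0.0752 and 0.468). T and NK cells, higher in 11 of 13, ended without SHAM replicates 1, 3 and 4 or PBS replicates 7 and 10 (0.144, 0.0862, 0.201, 0.515 and 0.133). Cell cycle genes were lower in 25 of 25 members (ended without SHAM replicates 4, 5 and 6 or PBS replicate 11: 0.187, 0.0997, 0.139 and 0.0680). Their mean scores differed little, at 5.81 ± 0.43 in PBS and 5.90 ± 2.12 in SHAM, where replicate 3 was at 1.62. Estrogen-responsive genes were lower in 12 of 14 (SHAM replicate 3 and PBS replicate 8: 0.275 and 0.0612) and mesothelium in 5 of 6 (SHAM replicate 3, PBS replicates 8 and 9: 0.175, 0.268 and 0.109). Interferon response was lower in 13 of 19 (SHAM replicates 2 and 3, PBS replicates 7, 8 and 10: 0.0627, 0.275, 0.0554, 0.234 and 0.489). Immediate early and heat shock genes were lower in 10 of 12 (SHAM replicates 2 and 3, PBS replicates 8 and 9: 0.0634, 0.410, 0.456 and 0.0948) and epithelium in 14 of 17 (SHAM replicates 3 and 4, PBS replicates 7 and 10: 0.447, 0.0700, 0.316 and 0.114). Each of these 8 lists had adjusted p = 0.677 with an estimated correlation. In all, 7 lists passed without SHAM replicate 3. Collagens and fibrosis, 27 of 29 members with a fitted fold above 0 and a median of 1.16, did not pass (adjusted p = 0.471), and their mean score was lower in PBS (3.50) than in SHAM (3.79). The squamous list did not pass (median -0.25, adjusted p = 0.308).

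By edgeR 0 of 17708 genes changed between PBS and SHAM, with 385 at an unadjusted p under 0.05 (269 higher, 116 lower), DESeq2 called 1 (Ighg1, an antibody heavy chain, named after its values were seen) and limma 0. Ighg1 was at the floor of -2.66 log2 CPM in all SHAM horns and above it in 1 PBS horn, so that call rests on 1 horn. Among the other genes with the smallest p, Stxbp6 was higher (log2 fold 0.87, SE 0.27) and Shmt2, a folate enzyme of mitochondria, Slc19a2, a thiamine transporter, and Pgam1, a glycolytic enzyme, were lower (-0.64, -0.71 and -0.69). The genes named in every contrast also did not pass, from Lif, a cytokine needed for implantation (-2.08, SE 1.06), to Col1a1 (1.61, SE 1.38), whose mean log2 CPM was lower in PBS (5.04 ± 3.84) than in SHAM (5.88 ± 1.41).

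HG vs PBS asks what the hydrogel alone did in damaged horns. Igf1, a growth factor of the uterine stroma, was at 6.99 ± 1.59 log2 CPM (SD, n = 6) in HG and 3.86 ± 2.36 (n = 5) in PBS (log2 fold 2.41, SE 1.08), and Hoxa10, a homeobox gene of the endometrial stroma, was at 5.23 ± 2.12 and 2.98 ± 2.32 (2.12, SE 1.05). Immediate early genes were higher in HG, with Fosb at 6.73 ± 1.15 against 3.71 ± 2.13 and Ier2 at 7.01 ± 0.73 against 6.14 ± 0.54. The chemokines Cxcl10 and Cxcl1 had log2 folds of 2.73 (SE 0.82) and 3.75 (SE 1.32), and the cytotoxic genes Prf1 and Gzmb 2.27 (SE 0.76) and 2.35 (SE 0.96). None of these passed, the smallest adjusted p of any gene being 0.991.

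In the list test 14 lists passed between HG and PBS, 13 of them higher in HG. Collagens and fibrosis were higher in 27 of 29 members (median log2 fold 1.30, and 2.23 without PBS replicate 10). Smooth muscle was higher in 14 of 14 (1.29, with 2.52 without PBS replicate 10 and 0.60 without HG replicate 16), and endometrial stroma in 10 of 11 (1.64, with 2.50 without PBS replicate 10 and 1.00 without HG replicate 14). Endothelium was higher in 13 of 13, with medians from 0.32 without HG replicate 14 to 1.42 without PBS replicate 10. The PBS horns were split, which leaving out 1 library at a time does not show. As differences from the SHAM mean, endothelium scores were 3.66 and 3.85 in PBS replicates 7 and 10. They were -2.48, -2.74 and -0.83 in PBS replicates 8, 9 and 11, and 0.95 to 4.07 in HG. Smooth muscle was at 2.66 and 4.00 in PBS replicates 7 and 10 and -2.18, -1.56 and 0.36 in 8, 9 and 11, against 0.24 to 4.95 in HG. Immediate early and heat shock genes were higher in 12 of 12 (0.87, and 0.50 without HG replicate 12), growth factors in 13 of 16 (0.91), and angiogenic factors in 12 of 13 (0.65, and 1.09 without PBS replicate 7). Cytokines in 13 of 19 and T and NK cells in 12 of 13 were higher, with medians from 0.38 and 0.37 without PBS replicate 8 to 1.25 and 1.40 without PBS replicate 7. None passed with an estimated correlation, where the smallest value was adjusted p = 0.324 with an estimated correlation. The exact permutation test of list scores passed none, with 2 at an unadjusted p under 0.05. Adjusted over the list alone, 0 members of any list were called.

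The remaining 5 calls between HG and PBS each ended when certain single horns were left out, some by a small margin. Macrophages were higher in 12 of 14 members and mast cells and eosinophils in 6 of 7, and both calls ended without PBS replicate 8 (adjusted p = 0.365 and 0.0509). Mesothelium was higher in 6 of 6, a call that ended without PBS replicate 8 or HG replicate 13 (0.0556 and 0.0635). The 9 of 9 higher adipocyte genes had a median of 10.15 without PBS replicate 7 and 1.10 without HG replicate 12, where the call ended (0.172). Epithelium was lower in 13 of 17 members, which ended without HG replicate 14 (0.0799). In the same order these lists had adjusted p = 0.607, 0.324, 0.366, 0.450 and 0.607 with an estimated correlation.

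By edgeR 0 genes changed between HG and PBS, with 597 at an unadjusted p under 0.05 (422 higher, 175 lower), and DESeq2 and limma also called 0. Among genes with the smallest p were Cfl2, an actin-severing factor of muscle (log2 fold 0.51, SE 0.13), Zbtb16, a transcription factor induced by steroid hormones (3.58, SE 0.96), and the potassium channel gene Kcnd3 (2.55, SE 0.70), and on the lower side Ubash3b (-0.49), Dync1h1, the dynein heavy chain (-0.50), and Ppia, cyclophilin A (-1.35). Ccn2 (1.90), Synm (1.43), Esam (0.78) and Erg (0.96) were among the leading members of their lists and did not pass.

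HG+ORG vs PBS asks the same of the hydrogel with organoids. Chemokine and macrophage genes had large fitted folds, but the value of HG+ORG replicate 18 carried most of each. Ccl3, a macrophage chemokine, had a log2 fold of 7.30 (SE 1.95) that was 1.89 (SE 1.11) without replicate 18, Ccl4 6.60 (SE 1.65) and 1.99 (SE 0.87), Lyz2 4.19 (SE 1.27) and 1.04 (SE 0.76), and Ctrl, a chymotrypsin-like protease gene of the pancreas, 6.50 (SE 1.60) and 0.55 (SE 0.42). The muscle genes Synpo2 and Pgm5 were lower with and without it, at -2.04 (SE 0.77) and -2.00 (SE 0.83) for Synpo2 and at -2.12 (SE 0.80) and -2.04 (SE 0.86) for Pgm5. None of these passed, the smallest adjusted p of any gene being 0.709.

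In the list test 8 lists passed between HG+ORG and PBS. Inflammatory cytokines were higher in 19 of 19 members (median log2 fold 3.29, and 1.99 without replicate 18) and macrophages and monocytes in 13 of 14 (2.32 and 0.61), and both calls held without it. Antigen presentation was higher in 12 of 13 members, with medians from 0.16 without PBS replicate 8 to 1.11 without PBS replicate 11. Immediate early and heat shock genes were higher in 11 of 12, which ended without replicate 18 (0.40, adjusted p = 0.0752). Smooth muscle was lower in 14 of 14 (-1.63), which ended without PBS replicate 10 (-0.73, adjusted p = 0.709). Collagens, higher in 25 of 29 members (1.09), ended without PBS replicates 8 and 9 or HG+ORG replicate 18 (adjusted p = 0.190, 0.183 and 0.283), with a median of -0.68 without the last. Matrix remodelling enzymes, higher in 13 of 18 (1.12), ended without PBS replicates 8, 9 and 10 or HG+ORG replicates 18 and 20 (0.395, 0.170, 0.0690, 0.992 and 0.0746), with a median of -0.30 without replicate 18. T and NK cells, higher in 11 of 13, ended without PBS replicates 8 and 9 or HG+ORG replicates 18 and 22 (0.0660, 0.0750, 0.149 and 0.0507). Without replicate 18 endothelium (median -2.80, adjusted p = 6.90e-05), endometrial stroma (-1.09, 0.0123) and erythrocytes (-1.73, 0.0207) were called lower and interferon response higher (0.26, 0.00791), none of which passed with all libraries. Without PBS replicate 7, 13 lists passed. The smallest value was adjusted p = 0.481 with an estimated correlation, and no list passed that or the exact permutation test of list scores. Adjusted over the list alone, 10 cytokine, 9 macrophage, 4 matrix enzyme, 2 neutrophil and 1 gland member were called. Those counts include replicate 18 and were not repeated without it.

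By edgeR 0 genes changed between HG+ORG and PBS, with 1079 at an unadjusted p under 0.05 (861 higher, 218 lower), or 489 without replicate 18, and DESeq2 and limma called 0 with and without it. Genes whose folds moved little without replicate 18 were Slc25a28, an iron carrier of mitochondria (0.59 and 0.52), Tspan31 (-0.49 and -0.45), Bnc2, a zinc finger gene of stromal cells (-1.55 and -1.76), Tmem106b (-0.73 and -0.68), Lif (2.23 and 2.46) and Vegfa (1.08 and 1.07). Ms4a7 (3.02 and 0.82), Atf3 (2.28 and 1.13), Fosb (1.88 and 1.50), H2-Eb1 (1.56 and 1.16), H2-Aa (1.49 and 1.05), Tgfb1 (2.03 and 0.19) and Adgre1 (1.79 and 0.37) had lower folds without it. Those of Thbs1 (2.94 and -0.43), Tnc (4.46 and -0.27), Col1a1 (1.52 and -1.15), Col3a1 (1.53 and -0.79) and Igf1 (0.87 and -1.35) changed sign.

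HG+ORG vs HG asks what the organoids added to the hydrogel. The muscle and stromal genes given here had fitted folds below 0, with and without replicate 18 where both are given, but no gene passed in edgeR (smallest adjusted p = 0.270, and 0.169 without replicate 18). Synpo2 was at 2.48 ± 1.19 log2 CPM (SD, n = 6) in HG+ORG and 5.61 ± 1.53 (n = 6) in HG (log2 fold -3.33, SE 0.78, and -3.30 without replicate 18), and the intermediate filament gene Synm had -2.90 (SE 0.74) and -3.28. Hoxa10 and Hoxa11, homeobox genes of the stroma, had -3.35 (SE 1.03) and -3.47 (SE 1.04), and Igfbp5, a binding protein of insulin-like growth factors, was at 4.62 ± 0.68 against 7.13 ± 0.59 (-2.49, SE 0.51). Igf1 had -1.54 (SE 0.98), and -3.75 (SE 0.90) without replicate 18.

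In the list test 12 lists passed between HG+ORG and HG, 4 higher and 8 lower. Smooth muscle was lower in 14 of 14 members (median log2 fold -2.88) and endothelium in 12 of 13 (-1.72, and -3.50 without replicate 18). Endometrial stroma was lower in 9 of 11 (-1.63, with -3.19 without replicate 18 and -0.72 without HG replicate 14), and growth factors in 10 of 16 (-0.74, with -1.44 and -0.30). Collagens, lower in 17 of 29 (median -0.14, mean 0.01), had a median of -2.14 without replicate 18, and the call ended without HG+ORG replicates 19, 20 and 22 (adjusted p = 0.0619, 0.0802 and 0.0700). Their median was above 0 without HG replicates 13 and 16 (0.14 and 0.06) or HG+ORG replicates 19, 20, 22 and 23 (0.11, 0.10, 0.13 and 0.07). With the smooth muscle score as covariate it was 1.37 and the list was called higher (adjusted p = 2.69e-06), so its direction depends on the setting. Antigen presentation was higher in 13 of 13 (0.73). Cytokines were higher in 16 of 19 (1.89) and macrophages in 12 of 14 (1.86), and both calls ended without replicate 18 (1.14 and 0.27, adjusted p = 0.157 and 0.819). Without replicate 18, 16 lists passed. Those that had not passed with it were epithelium (median 0.51, adjusted p = 6.28e-06), estrogen-responsive genes (1.04, 0.0188) and Wnt targets (0.59, 0.0273), called higher, and angiogenic factors (-0.79, 0.000131), erythrocytes (-1.56, 0.0177), immediate early and heat shock genes (-0.27, 0.0273) and T and NK cells (-0.85, 0.0444), called lower. The smallest value was adjusted p = 0.313 with an estimated correlation, and no list passed that or the exact permutation test of list scores, which gave smooth muscle scores of 1.89 and 4.61 an adjusted p of 0.251. Without replicate 18 the exact permutation test gave score differences of -3.32 for endothelium, -1.15 for growth factors and -1.04 for angiogenic factors, each with an adjusted p of 0.0837. Adjusted over the list alone, and with replicate 18 included, 11 smooth muscle, 7 macrophage, 6 cytokine, 6 adipocyte, 5 matrix enzyme, 4 stromal, 4 neutrophil, 2 implantation and 1 progesterone-responsive member were called. The neutrophil list itself did not pass (median 4.15, adjusted p = 0.118, and 1.69, adjusted p = 0.563, without replicate 18).

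Further calls between HG+ORG and HG ended without single horns. Adipocyte genes were lower in 9 of 9 members (-6.80), which ended without HG replicate 12 (-3.55, adjusted p = 0.340), and mesothelium in 6 of 6, which ended without HG replicates 13 and 16 (0.104 and 0.0580). Progesterone-responsive genes were lower in 7 of 9, which ended without HG replicates 14 and 17 or HG+ORG replicates 18 and 21 (0.523, 0.103, 0.157 and 0.129). Interferon response was higher in 16 of 19, which ended without HG replicates 13, 14, 16 and 17 (0.0693, 0.130, 0.0922 and 0.390) or HG+ORG replicates 19, 20 and 21 (0.578, 0.214 and 0.537). The values were adjusted p = 0.633 with an estimated correlation for adipocytes, mesothelium and progesterone-responsive genes and 0.748 for interferon response.

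By edgeR 0 genes changed between HG+ORG and HG, with 1737 at an unadjusted p under 0.05 (918 higher, 819 lower). DESeq2 called 170 (39 higher, 131 lower), limma 281 (44 higher, 237 lower), and 40 were called by both. Without replicate 18 DESeq2 called 723 (33 higher, 690 lower), 133 of them among the 170, and limma 695. The DESeq2 calls included 6 smooth muscle genes, all lower (Synpo2, Synm, Pgm5, Mylk, Cnn1 and Myh11), and Hoxa10, Hoxa11 and Gli1, also lower, and on the higher side Lyz2 and Cd68 of the macrophage list, Cxcr2 of the neutrophil list and the cytokines Il1b and Cxcl5. Genes with the smallest p in edgeR were Bnc2 (-2.42, SE 0.44), Kcnd3 (-3.49, SE 0.69) and Igfbp5 on the lower side, and Lpin2, a lipid phosphatase gene (0.99, SE 0.24, and 0.83 without replicate 18), on the higher. The folds of Ctrl (6.22 and 0.25), Ccl4 (5.90 and 1.28), Ccl3 (6.47 and 1.03), Lyz2 (3.49 and 0.33), Cd14 (2.03 and 0.99) and Tgfb1 (1.75 and -0.11) rested on replicate 18. Psmb8 and Psmb9, subunits of the immunoproteasome, were at 0.73 and 0.55 with it and 0.69 and 0.57 without. Nr2f2 (-0.63 and -0.55), Tek (-2.58 and -3.50) and Esam (-1.43 and -2.42) were lower without passing, with and without replicate 18, and Col1a1 went from 0.30 to -2.37 without replicate 18.

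HG vs SHAM and HG+ORG vs SHAM set the treated horns against SHAM. Muscle, vessel, matrix and lymphoid lists had higher scores in the horns with hydrogel alone than in SHAM horns, though edgeR called 0 of their genes. The fitted fold was above 0 in 14 of 14 smooth muscle members, with Myh11, the smooth muscle myosin, at 6.31 ± 2.18 log2 CPM (SD, n = 6) against 3.11 ± 0.56 (n = 6) and Acta2 at 7.51 ± 2.20 against 4.20 ± 0.66. It was above 0 in 12 of 13 endothelial members, with Pecam1 at 6.00 ± 1.00 against 2.67 ± 1.21 and Flt1 as the exception (4.78 ± 0.73 against 4.05 ± 1.80, fitted log2 fold -0.52). It was above 0 in 27 of 29 collagen and fibrosis members, with Col3a1 at 9.16 ± 1.79 against 6.41 ± 1.48. It was above 0 in 6 of 6 B and plasma cell members, with Igkc, the kappa light chain, at 3.78 ± 2.95 against -0.49 ± 1.06 and Jchain at 2.10 ± 2.86 against -1.38 ± 0.69. These 4 lists had adjusted p = 0.210, 0.221, 0.324 and 0.210 with an estimated correlation.

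Of the 18 lists that passed the preset test between HG and SHAM, 14 higher and 4 lower, 10 also passed the exact two-sided permutation test of list scores and 0 the test with an estimated correlation. With the smooth muscle score as covariate 7 lists were called, 3 higher and 4 lower, and collagens, endothelium, macrophages and cytokines were not (adjusted p = 0.271, 0.233, 0.520 and 0.952). In the permutation test the score differences and adjusted p of those 10 were 2.68 for smooth muscle, 2.87 for endothelium, 2.10 for B and plasma cells, 1.18 for T and NK cells, 1.65 for mast cells and eosinophils, 1.01 for growth factors and 1.04 for angiogenic factors (each 0.0269), 1.94 for collagens and 2.45 for erythrocytes (0.0349), and 1.03 for macrophages (0.0377). All 6 HG horns lay above all SHAM horns for B and plasma cells, 5 of 6 for smooth muscle, endothelium, collagens, T and NK cells, growth factors and angiogenic factors, 4 of 6 for mast cells and macrophages, and 2 of 6 for erythrocytes. The median log2 folds were 3.56 for smooth muscle, 2.95 for endothelium, 3.60 for B and plasma cells, 1.53 for T and NK cells, 2.62 for mast cells and eosinophils, 1.24 for growth factors, 0.84 for angiogenic factors, 2.54 for collagens, 2.34 for erythrocytes and 1.08 for macrophages. The T and NK cell median was 0.92 without HG replicate 14 and the angiogenic factor median 1.28 without SHAM replicate 3. Endometrial stroma (2.88) and mitochondrially encoded genes (0.79) were higher in the preset test alone. Epithelium (-0.54, and -0.32 without SHAM replicate 3), estrogen-responsive genes (-1.07, and -0.40 without it) and interferon response were lower in it, the last with medians from -0.53 without HG replicate 12 to -0.20 without HG replicate 16. Adjusted over the list alone, 14 smooth muscle, 10 endothelial, 8 stromal, 6 T and NK cell, 5 erythrocyte, 4 B and plasma cell, 4 mast cell, 4 angiogenic, 2 implantation, 1 growth factor and 1 mesothelial member were called.

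No list passed between HG and SHAM with an estimated correlation, where the smallest value, shared by smooth muscle, T and NK cells, stroma, mast cells, B and plasma cells and growth factors, was adjusted p = 0.210 with an estimated correlation. The values for collagens, endothelium, erythrocytes, angiogenic factors and macrophages were adjusted p = 0.324, 0.221, 0.221, 0.245 and 0.536 with an estimated correlation. The number of lists past the permutation test was 0 without SHAM replicates 1, 3 or 4, 3 without HG replicate 16 and 4 without SHAM replicates 5 or 6, with adjusted p at most 0.0691 for these 10 lists in any of those tests. With the scores of SHAM replicates 5 and 6 averaged it was 4, and smooth muscle (adjusted p = 0.0523) and B and plasma cells (0.0502) were among those that no longer passed. By edgeR 0 genes changed, with 1996 at an unadjusted p under 0.05 (1620 higher, 376 lower), while DESeq2 called 292 (283 higher, 9 lower), limma 1299 (930 higher, 369 lower), both together 210, and edgeR on those groups alone 386 (383 higher, 3 lower). With HG+ORG replicate 18 left out of the fit DESeq2 called 976 (884 higher, 92 lower). The DESeq2 calls held 11 of the 14 smooth muscle genes and Igkc, Jchain and Ighm, all higher. The preset test also called immediate early and heat shock genes (9 of 12 members higher), cytokines (12 of 19 higher) and cell cycle genes (25 of 25 lower), calls that single horns ended. They ended for immediate early genes without SHAM replicates 1, 5 and 6 or HG replicates 12, 13 and 16 (adjusted p = 0.0747, 0.113, 0.120, 0.269, 0.123 and 0.0699). They ended for cytokines without SHAM replicates 1, 4, 5 and 6 (0.0787, 0.213, 0.127 and 0.106) or HG replicates 12, 13 and 15 (0.293, 0.0730 and 0.0618). For cell cycle they ended without SHAM replicates 1, 2, 4, 5 and 6 (0.0560, 0.0731, 0.375, 0.237 and 0.251) or HG replicates 12, 14 and 15 (0.242, 0.262 and 0.213). The mean cell cycle scores were close, at 5.81 ± 0.84 in HG and 5.90 ± 2.12 in SHAM (exact permutation p = 0.952). In the same order these lists had adjusted p = 0.603, 0.660 and 0.748 with an estimated correlation. Adipocytes, glands and antigen presentation did not pass, with medians above 0 (1.35, 0.35 and 0.23) and a test direction downward.

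With organoids no difference from SHAM was called in the muscle and vessel lists, with smooth muscle scores of 1.89 and 1.93 (adjusted p = 0.925 in the preset test) and endothelium scores of 2.09 and 1.84 (adjusted p = 0.344). Macrophages and monocytes (14 of 14 members, median log2 fold 2.79, and 1.03 without replicate 18), inflammatory cytokines (19 of 19, 2.75 and 1.78), antigen presentation (13 of 13, 0.88 and 0.56), T and NK cells (11 of 13, 0.66 and 0.36) and B and plasma cells (4 of 6, 2.93 and 2.76) were higher in HG+ORG than SHAM with and without that library. Cd3g, a chain of the T-cell receptor complex, was at 0.50 ± 1.57 log2 CPM (SD, n = 6) against -1.69 ± 0.48 (n = 6), and C1qb, a complement gene of macrophages, at 6.53 ± 2.13 against 4.15 ± 1.30. The preset test passed 14 lists, 9 higher and 5 lower. Adipocyte genes were lower in 9 of 9 members (-5.17), with and without any 1 library. The smallest value was adjusted p = 0.467 with an estimated correlation, and no list passed that or the exact permutation test of list scores, in which B and plasma cells came nearest (difference 1.79, adjusted p = 0.126). Adjusted over the list alone, 11 cytokine, 10 macrophage, 8 matrix enzyme, 5 collagen, 4 T and NK cell, 4 B and plasma cell, 3 adipocyte, 2 antigen presentation, 2 neutrophil, 1 gland and 1 stromal member were called. Those counts, too, include replicate 18 and were not repeated without it. Uterine glands (0.14), implantation and receptivity (0.05), Wnt targets (0.22) and ciliated and oviduct cells (0.33) did not pass (adjusted p = 0.925, 0.925, 0.688 and 0.213). Without replicate 18 Wnt targets (0.34, adjusted p = 0.0173) and mitochondrially encoded genes (0.54, adjusted p = 0.0390) were called higher.

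By edgeR 0 genes changed between HG+ORG and SHAM, with 1754 at an unadjusted p under 0.05 (1432 higher, 322 lower). DESeq2 called 94 (92 higher, 2 lower) and limma 1. Without replicate 18 the unadjusted count was 608, DESeq2 called 2 and limma 0. Leaving out replicate 18 ended the calls of collagens (27 of 29 members higher, median 2.19, and 0.22 without it, adjusted p = 0.903), matrix enzymes (17 of 18 higher, 1.69 and 0.18, adjusted p = 0.458), erythrocytes (5 of 5 higher, 1.51 and 0.68, adjusted p = 0.0633) and epithelium (16 of 17 lower, -0.33 and -0.13, adjusted p = 0.587). The epithelium median was also -0.19 without SHAM replicate 3 and -0.60 without HG+ORG replicate 21, and the erythrocyte median 2.60 without SHAM replicate 2. Mast cells and eosinophils (7 of 7 higher) ended without SHAM replicate 3 or HG+ORG replicate 20 (adjusted p = 0.0516 and 0.0564). Estrogen-responsive genes (10 of 14 lower) ended without SHAM replicate 3 or HG+ORG replicates 18, 20 and 22 (0.430, 0.672, 0.0866 and 0.192), and cell cycle (25 of 25 lower) without SHAM replicates 4 and 5 or HG+ORG replicate 21 (0.0990, 0.0580 and 0.971). The mean cell cycle scores were 5.46 ± 1.91 in HG+ORG and 5.90 ± 2.12 in SHAM. Mesothelium (5 of 6 lower) ended without SHAM replicates 3 and 4 (0.317 and 0.0520) or HG+ORG replicates 19, 20, 22 and 23 (0.0864, 0.170, 0.0743 and 0.0736). These 8 lists had adjusted p = 0.504 to 0.723 with an estimated correlation.

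**Figure D2:**
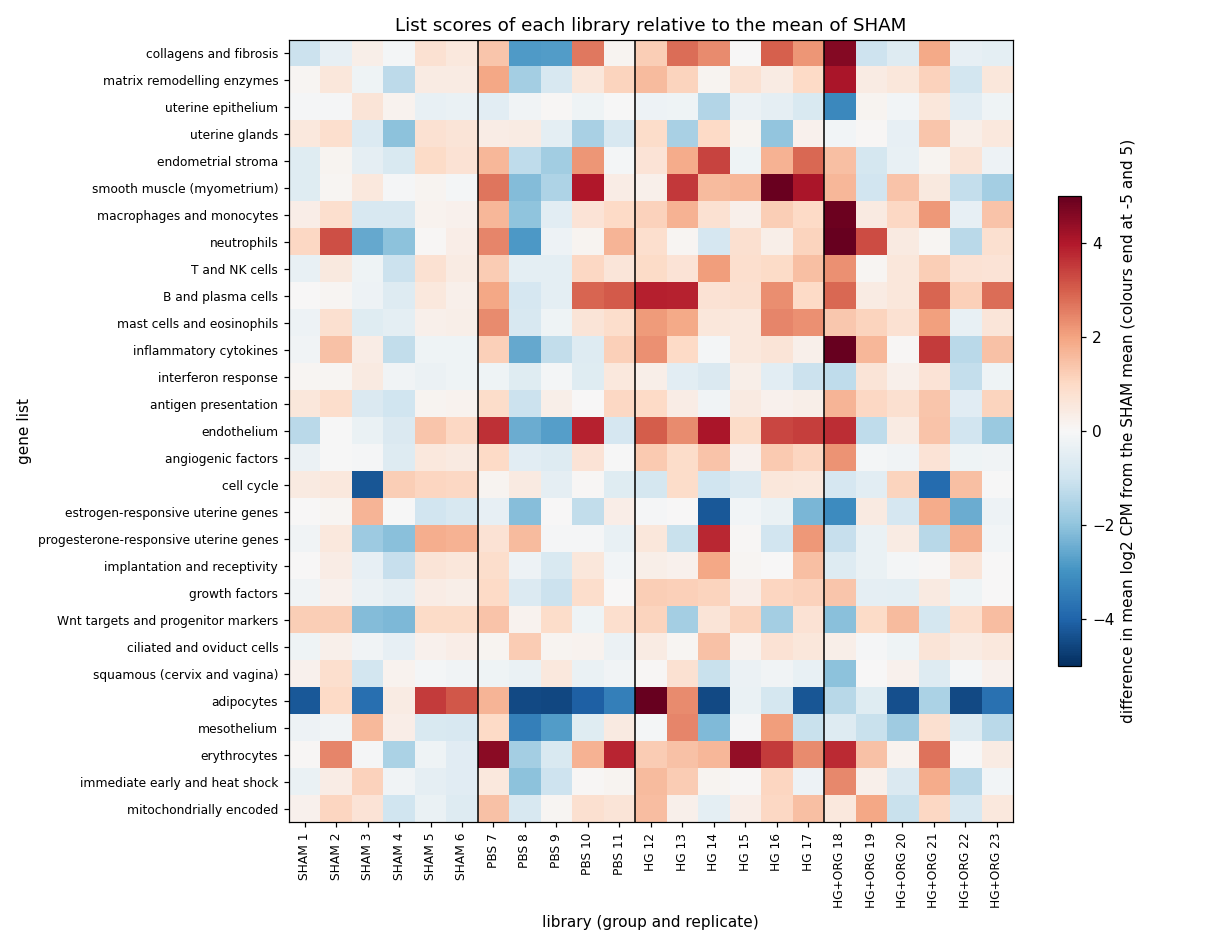
Difference of each library's list score (mean log2 CPM of the list) from the SHAM mean, for 29 gene lists (vertical axis) in 23 libraries ordered by group (horizontal axis); red is higher and blue lower, and colours end at -5 and 5. Muscle and vessel lists are mostly red in HG, where the mean scores are 4.61 and 4.71 against 1.93 and 1.84 in SHAM, and horns of every group differ among themselves.

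Whether hydrogel or organoids turned back the change from SHAM to PBS was asked over all 17708 tested genes. The slope of the change from PBS to HG on the change from SHAM to PBS was -0.241 with shared PBS libraries, against -0.542 in simulated groups with no change, and 0.286 with disjoint PBS libraries, against 0.00293 in the simulation. For HG+ORG the slopes were -0.257 with shared and 0.292 with disjoint PBS libraries, against -0.538 and 0.00520. A turning back would give a negative slope. Neither disjoint slope was negative, but each took both signs over the 20 assignments of PBS libraries. These slopes can therefore neither show nor exclude a turning back. The covariances with shared PBS libraries were -0.0377 for HG and -0.0403 for HG+ORG, against -0.152 and -0.151 in the simulation. The slope for HG ran from -0.380 to 1.27 over the 20 assignments of PBS libraries and was -0.0615 without PBS replicate 10, and that for HG+ORG ran from -0.0261 to 0.903. Since edgeR called 0 genes between PBS and SHAM (385 at an unadjusted p under 0.05, DESeq2 1, limma 0), there were no called genes whose return could be counted.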

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

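The tests on HG+ORG replicate 18, the splits with SHAM replicates 5 and 6 summed, the permutation tests of list scores and the comparison of all injured horns with SHAM were chosen only after the results were seen. In 400 groups of values tested for a horn far from the others of its group, 28 held such a horn, while chance alone gives about 1 in 20.

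HG+ORG replicate 18 lay far from the other HG+ORG horns in several values. Its epithelial score was 5.38 against 8.08 for the next horn and its angiogenic factor score 4.83 against 3.28. In log2 CPM, Tgfb1 was at 8.09 in it (next 4.53), Esr1 at 3.82 (next 8.07), Esam at 5.85 (next 3.42), Ctrl at 9.39 (next 1.37), Ms4a7 at 8.45 (next 4.70) and Thbs1 at 11.71 (next 6.48). HG+ORG replicate 22 was lowest in Psmb8 (6.55, next 7.01) and highest in Hoxa11 (3.91, next 1.72).

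Among SHAM horns, replicate 3 was lowest in the cell cycle score (1.62, next 6.34) and in Plk1 (0.71, next 5.76), Rrm2 (2.00, next 5.87) and Mki67 (0.62, next 7.62). SHAM replicate 4 had the lowest total (7920920 counts) and was lowest in Jchain (-2.66, the floor, next -1.49), Ccn2 (1.01, next 3.52), Lpin2 (4.15, next 5.05) and Psmb9 (4.66, next 5.43). SHAM replicate 2 was highest in Hbb-bs (6.45, next 3.75) and SHAM replicate 1 lowest in Kcnd3 (-0.26, next 0.20).

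In the other groups, PBS replicate 7 was highest in the adipocyte score (5.57, next 0.48), Lep (1.35, next -2.66) and Plin1 (3.93, next -1.44), and PBS replicate 9 in the squamous score (1.39, next 0.70). HG replicate 15 was lowest in the growth factor score (2.71, next 3.43) and in Tgfb1 (3.37, next 4.11), and HG replicate 12 highest in Cxcl10 (5.99, next 3.37).

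For the distance of HG+ORG replicate 18 from the other libraries, the tables argue against low depth, since its total was 11.5 M counts and those of the 23 libraries ran from 7.92 to 14.9 M. Its 10 most abundant features held 15.0% of counts, a high share in the series: HG+ORG replicate 19, with 15.4%, had a mitochondrially encoded share of 11.4% against 3.37%. Its TMM factor, 0.702, was the lowest of the 23. A few genes taking most of the counts would lower all others alike, which leaves the difference between list scores about unchanged. Without the 34 features among the 10 most abundant of any library, its macrophage minus epithelium score was 2.85, against -6.93 to -2.88 in the other libraries (SD 1.10). Such a lowering alone would not give that difference. It reuses the scores by which the library was noticed, however, so its outcome was known beforehand and it is no independent test. What sets it apart stays open, and no biological explanation for it was tested.

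The smooth muscle and endothelium mean was higher in HG than SHAM by 2.77 (SE 0.53, n = 6 and 6). With the estrogen-responsive and cell cycle scores as covariates the difference was 2.60 (SE 0.62, approximate permutation p = 0.00649 over 924 splits). These covariates took up little of the difference. That p is not adjusted for the choice of these lists, which had the largest score differences between HG and SHAM (2.68 and 2.87). It also counts SHAM replicates 5 and 6 as separate horns, so no conclusion is drawn from it. The covariates are only proxies of estrous stage, so a difference in stage stays open. Where covariates were used, the labels were permuted with the covariates held fixed, so those p-values are approximate. A lower epithelial share that raises all other cell types alike cannot be told apart, since the difference from the mesothelium and adipocyte mean was 2.86 with a wide spread (SE 1.32, exact permutation p = 0.0714). A shared amount of muscle and vessel tissue may underlie the higher collagen, stroma and growth factor scores, whose difference of 1.56 (SE 0.41) was -0.26 (SE 0.44, approximate permutation p = 0.569) with the smooth muscle and endothelium mean as covariate. That covariate itself differed between the groups, so any change shared by these lists would give the same drop. The drop therefore cannot decide the cause. How much deep tissue was pressed out with the endometrium and the effect of the hydrogel itself stay open.

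The B and plasma cell score was higher in the 17 injured horns than in the 6 SHAM horns by 1.76 (SE 0.61, exact permutation p = 0.00945 over 100947 splits), with 14 of 17 above every SHAM horn, but the adjusted p over the 29 lists was 0.216. With the smooth muscle and endothelium mean as covariate the difference was 1.42 (SE 0.57, approximate permutation p = 0.0209). This list had the smallest p of the 29 and did not pass after adjustment. That covariate p is not adjusted for the choice of list, so it cannot decide whether more muscle and vessel tissue is the cause. Blood in the sample cannot be told apart, since with the erythrocyte score as covariate the difference was 1.16 (SE 0.62, approximate permutation p = 0.0761). The injury itself could also account for the difference, which was not tested apart from these.

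Other splits of the same libraries show whether chance alone can give such counts. With edgeR the real count of genes was 0 in every comparison, which 50 of 50 splits reach by construction, so this count says nothing about chance. The highest counts of the other splits were 0 for PBS vs SHAM, 14 for HG vs PBS, 0 for HG+ORG vs PBS, 1236 for HG+ORG vs HG, 0 for HG vs SHAM and 2627 for HG+ORG vs SHAM. Why some splits call many more genes than the real split was not tested. For lists past the preset-correlation test in HG vs SHAM, 1 of 50 splits gave as many as the real 18 (highest other 16), the real split itself. With SHAM replicates 5 and 6 summed, however, 3 of 50 splits gave at least the real 16 (highest other 17), so chance cannot be excluded once that pair counts as 1 library. Nor can it be excluded for PBS vs SHAM (22 of 50 splits gave at least 13, highest other 22), HG vs PBS (20 of 50, at least 14, highest other 20), HG+ORG vs PBS (45 of 50, at least 8, highest other 20), HG+ORG vs HG (21 of 50, at least 12, highest other 17) or HG+ORG vs SHAM (11 of 50, at least 14, highest other 19). The same holds for the genes called by DESeq2, with 3 of 30 splits giving at least 292 for HG vs SHAM (highest other 479) and 8 of 30 giving at least 170 for HG+ORG vs HG (highest other 826).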

How the results depend on the processing

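The permutation tests of list scores, the epithelium score as covariate, the sum or mean of SHAM replicates 5 and 6 and the fits leaving out HG+ORG replicate 18 together with another change were chosen only after the data had been seen. Of the 79 list calls, all 79 kept their direction and side of the threshold under relative log expression factors, 78 with no low-count filter, 74 with SHAM replicates 5 and 6 summed, 64 with the estrogen-responsive score, 56 with the epithelium score and 47 with the smooth muscle score as covariate, 44 with limma, 10 in the permutation test and 0 with an estimated correlation. The number of lists called was 0 with an estimated correlation in each of the 6 comparisons, against 13, 14, 8, 12, 18 and 14 with the preset value for PBS vs SHAM, HG vs PBS, HG+ORG vs PBS, HG+ORG vs HG, HG vs SHAM and HG+ORG vs SHAM. An allowance for correlated members makes that test stricter by construction. In the exact permutation test it was 10 for HG vs SHAM and 0 for the other 5, and 0 leaving out HG+ORG replicate 18 for HG+ORG vs PBS, HG+ORG vs HG and HG+ORG vs SHAM. With limma it was 8 for PBS vs SHAM, 3 for HG+ORG vs PBS and 7 for HG+ORG vs SHAM. It was 7 for HG vs SHAM with the smooth muscle score as covariate, and 9 for HG+ORG vs SHAM with SHAM replicates 5 and 6 summed and replicate 18 left out. Without 1 library the number ran from 7 to 16 for PBS vs SHAM, 14 to 17 for HG vs PBS, 6 to 13 for HG+ORG vs PBS, 10 to 16 for HG+ORG vs HG, 15 to 19 for HG vs SHAM and 11 to 16 for HG+ORG vs SHAM, and from 0 to 11 in the permutation test of HG vs SHAM, which passed 4 with SHAM replicates 5 and 6 averaged. For genes, edgeR called 0 in every comparison without any 1 library, and 386 for HG vs SHAM on the compared groups alone. DESeq2 called 1 for PBS vs SHAM, 170 for HG+ORG vs HG, 292 for HG vs SHAM and 94 for HG+ORG vs SHAM, and leaving out replicate 18 it called 2, 723, 976 and 2, of which 1, 133, 291 and 2 were among those called with all libraries. Limma called 281 for HG+ORG vs HG, 1299 for HG vs SHAM and 1 for HG+ORG vs SHAM, and leaving out replicate 18 it called 695 for HG+ORG vs HG and 1469 for HG vs SHAM. Called lists whose direction turned are given by their median log2 fold. With limma these were, for PBS vs SHAM, epithelium (0.0699), interferon response (0.20), endothelium (-0.67), estrogen-responsive genes (0.40) and immediate early genes (0.13), for HG+ORG vs PBS collagens (-0.28) and matrix enzymes (-0.0802), for HG+ORG vs HG macrophages (-0.14), and for HG+ORG vs SHAM collagens (-0.74), epithelium (0.0894) and estrogen-responsive genes (0.28). With the smooth muscle score as covariate they were, for PBS vs SHAM, smooth muscle (-0.14) and endothelium (-0.66), for HG vs PBS macrophages (-0.12), and for HG+ORG vs PBS smooth muscle (0.10). For HG+ORG vs HG they were collagens (1.37), smooth muscle (0.10) and mesothelium, whose median stayed below 0 (-0.12) while its test direction turned upward. For HG vs SHAM they were collagens (0.0387), smooth muscle (-0.16), macrophages (-0.0642), cytokines (-0.40) and immediate early genes (0.0149), the last with a test direction opposite to its median, as for collagens. A covariate built from the smooth muscle list removes that list's own difference by construction. With the estrogen-responsive score PBS vs SHAM epithelium was at 0.0142, and with the epithelium score HG vs PBS epithelium was at 0.11 and HG+ORG vs SHAM estrogen-responsive genes at 0.14. Without HG+ORG replicate 18, collagens were at -0.68 in HG+ORG vs PBS (-0.68 also with SHAM replicates 5 and 6 summed, and up to 2.34 without another library) and at 0.22 in HG+ORG vs SHAM with a test direction downward (up to 2.47 without another library). The test direction of PBS vs SHAM endothelium turned without PBS replicate 7 or 10, with medians that ran from 1.48 to 2.89 over the left-out libraries. The slope of the change from PBS to HG on that from SHAM to PBS ran from -0.0615 to 0.467 without 1 library, and that for HG+ORG from 0.170 to 0.377. Apart from what construction explains, the cause was not tested. With no gene called between PBS and SHAM, a slope over called genes gave no value. Of 2831 alternative values of named genes, 108 had the other sign, with no call in either setting. At the depths of these libraries edgeR recovered 10 to 36% of simulated 2-fold changes, and the part of depth in this was not told apart from the number of horns or their spread.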

Other observations

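The genes named here other than Esr1, Pgr, Ctrl, Iglc2 and the list members Jchain, Igkc and Ighm were chosen after their values were seen, as was the comparison of all injured horns with SHAM. In HG+ORG replicate 18, some macrophage genes were far above the other 22 libraries, though Arg1, at 9.73 log2 CPM, was not (others up to 12.15): Mmp12 was at 12.62 log2 CPM (others at most 6.64), Gpnmb at 13.18 (7.12), Spp1 at 14.88 (10.31), Trem2 at 9.87 (4.54) and Ctsk at 11.66 (4.79). Genes best known from the pancreas were too, with Ctrl at 9.39 (others at most 1.47), Cela1 at 10.80 (2.87) and Rnase1 at 8.53 (2.97). Epithelial genes and steroid receptors were below every other library, with Krt8 at 7.12 (others at least 8.69), Epcam at 7.13 (9.11), Esr1 at 3.82 (8.07) and Pgr at 2.58 (5.31). Its mitochondrially encoded share was 3.37%, within the range of the series.

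Immunoglobulin transcripts lay above every SHAM horn in most of the 17 injured horns, in 14 for Jchain, 13 for Ighm, 12 for Igkc and 12 for Iglc2. Ighg1, the gene DESeq2 called between PBS and SHAM, was at the floor of -2.66 in all SHAM horns and above it in 8 injured horns, 1 PBS, 4 HG and 3 HG+ORG. Over the 29 lists, 4 differed between injured and SHAM horns at an unadjusted p under 0.05 in the exact permutation test and 0 after adjustment. The cell cycle score was lowest in SHAM replicate 3 (1.62) and lowest among HG+ORG horns at 2.04, against group means of 5.90 and 5.46.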
